A study of Lactiplantibacillus plantarum with 21 samples.

How the data were processed

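Transcripts of Lactiplantibacillus plantarum were measured on 21 two-colour DNA microarrays. Per the labels, total RNA from 12 batch cultures was labelled with Cy3 or Cy5 and hybridised in pairs. The cultures fell into 4 groups of 3: the strain with plasmid pNZ7021 or with plasmid pNZ7026, each grown with or without p-aminobenzoate (pABA). The labels call the 3 cultures of a group biological replicates. Of the arrays, 8 paired cultures within pABA medium, 8 within pABA-free medium, and 5 paired cultures across the media.

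The deposited scanner values are linear spot intensity values, per the file headers, with a foreground and a local background for each dye and a quality flag, made with quantification software version 5.6.0. The deposited series table holds log2 ratios of the same arrays. Per the submitters' processing notes limma was used, with no version or model given in the sources used here. Set against the background-subtracted scanner values over 2874 bright probes, most columns of that table ran as log2 of Cy3 over Cy5 with a slope near -0.8, so its direction was the opposite of the Cy5 over Cy3 ratios used here and its scale was compressed. The column medians for arrays 1 to 21 were 0.11, 0.045, 0.11, -0.072, 0.27, -0.29, 0.11, -0.018, 0.048, 0.10, 0.15, 0.094, 0.13, 0.11, -0.021, 0.23, 0.24, 0.093, 0.27, 0.0066 and 0.034. How the authors centred and compressed these values stayed unknown, and they served only as an alternative.

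Each array held 10807 spots: 9553 gene spots, 1200 control or blank spots and 54 spots of 43 other probes. The gene spots covered 7968 probes of 2851 loci, named by locus as in the array's files. The platform's annotation table gave 1 symbol for 1146 probes, several for 0, and none for the other 8461 of 9607 probes of the deposited table. These symbols named 337 loci, and 3 symbols stood on 2 loci each. All other loci are named by their locus tag only. The reference gene table was of another strain and was not used here, so no coordinates are given.

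The median foreground of gene spots was 895 to 1207 in Cy3 and 814 to 1154 in Cy5 over a local background of 473 to 489. Of the gene spots, 96.5% to 99.4% in Cy3 and 87.6% to 99.5% in Cy5 exceeded their background by 2 SDs, and 1.81% to 2.94% per array carried the poor-quality mark. The number of arrays limits the precision. The median standard error of a log2 fold change was 0.10 for either strain comparison, 0.11 for either pABA comparison and 0.14 for the interaction.

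The background was corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50), and the log2 ratios were normalised within each array by loess (4 iterations, control and poor spots given no weight). Control spots and poor spots were left out, spots of a probe were averaged, and the mean was taken over the probes of a locus. Probes entered if they were above background in at least 50% of the channels of at least 1 group, which left 2843 loci and 7898 probes. Over 2641 loci with 2 or more probes, the median SD of the probes' log2 fold changes between the strains was 0.043. No named locus lay at background in all channels of a group. In pNZ7021 with and without pABA, however, lp_p2_02 was above it in only 2 of 8 and 1 of 8 channels, and lp_p2_01 in 16 of 24 and 15 of 24, so their log2 values are given without a fold.

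The arrays entered a generalised least squares fit of the 4 groups with a dye term and the culture as a random effect, since up to 4 arrays shared a culture. The variance ratio of culture to array error, estimated once over all genes, was 0.546, and the fit left 13 residual degrees of freedom. These degrees of freedom count arrays, not cultures, and 1 ratio served every gene. A locus that varied more between cultures than this ratio allows could therefore be called too readily. Counts from a fit over culture levels are given beside the main counts for that reason. Tests were limma's moderated tests (prior degrees of freedom 3.26) with Benjamini-Hochberg adjustment over all loci and a threshold of 0.05. The comparisons were the strain effect (pNZ7026 over pNZ7021) in each medium and averaged over media, the pABA effect (with over without) in each strain and averaged over strains, and their interaction. Values per culture were least-squares levels over the arrays, and groups of 3 cultures were compared by a two-sided exact permutation test, whose smallest possible p is 0.1.

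Of 21 gene lists fixed before the data were examined, 15 had at least 4 measured genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation was an alternative. At the preset correlation 51 calls were made over the 7 comparisons, and 4 held with an estimated correlation, all of the pyrimidine list: the strain effect in each medium and averaged, and the pABA effect averaged over strains. In that list carB (lp_2700), pyrE and pyrF are neighbours by locus number with closely similar culture levels. The estimate of 0.0497 averages over the whole list and counts them as nearly independent, so these calls can be too lenient. The folate cluster list had too few complete measurements for an estimated correlation.

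The genes named in the text followed a rule set before the data were examined. For each comparison except those averaged, they were every measured locus of the folate cluster, up to 10 loci with the largest fold change in each direction that passed the threshold and kept their sign whichever of the 6 cultures was left out, and the 3 members with the smallest p of each list past the threshold. Where no locus passed, the 3 with the smallest p in each direction were named as not past the test. Loci named outside this rule are said to be so.

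The planned fit held all 21 arrays, and 17 were used. The scans of arrays 5 and 6 held identical values, and the series table could not assign them by the rule set beforehand: the scan matched the column of array 6 at r = 0.995 but with the sign turned. Both arrays were left out. The scans of arrays 12 and 13 matched the table's columns of arrays 4 and 5 (r = -0.994 and -0.992) and not their own (r = -0.25 and -0.052), and were left out after the data were seen. As a result, culture 3 of pNZ7021 without pABA rested on 1 array. The scan of array 4, 1 of the 2 arrays of culture 3 of pNZ7021 with pABA, was kept as labelled, although it matched its own column at only r = -0.882 and that of array 6 at -0.900, and the scan of array 12 matched column 4 better. The labels and the design text gave opposite dye orders for arrays 7 and 15, and the labels were followed.

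The fit was tested on simulated data with 100 changed genes at each size among 2847. For the strain effect with pABA it recovered 83% of changes of 0.5 and 100% of changes of 1 on the log2 scale, with 3.68% of its calls false. For the pABA effect in pNZ7021 it recovered 79% and 100%, with 3.24% false, and for the interaction 48% and 92%, with 4.11% false. With arrays taken as independent, the simulated strain effect gave 69 false calls in place of 7. The simulated data followed the fitted model, with a variance ratio of 0.5 for every gene and with independent genes. They held no outlying culture and no scan under a wrong label, so these rates need not hold for the real data.

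Alternatives fixed before the data were examined were the background correction, the normalisation, the filter on dim probes, the median over probes, no dye term, arrays as independent, a fit over culture levels, a replicate block, the design text's dye orders, arrays within a medium only, each reading of the doubled scan, the series table, scan batch and slide, stricter thresholds, and each of the 12 cultures left out in turn. Other readings of the scans of arrays 12 and 13, the fits without array 4 or array 20, array 7 alone in the design text's order, poor spots kept, and the series table with medians set to 0 were chosen after seeing the data.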

Results

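The series measured how the transcriptome of Lactiplantibacillus plantarum, a lactic acid bacterium, differed between a strain carrying plasmid pNZ7021 and one carrying pNZ7026, and how p-aminobenzoate (pABA) in the medium changed it. pNZ7026 is known to carry the folate gene cluster of this species, and pNZ7021 is the vector without it. pABA is a building block of folate that the cell joins to a pterin. Each of the 4 combinations of strain and medium had 3 batch cultures, and 17 of the 21 arrays, with 2843 loci tested, entered the comparisons. On each array 87.6% or more of the gene spots in either dye lay above background. Fold changes between strains are pNZ7026 over pNZ7021, and the deposited ratios run Cy3 over Cy5, opposite to the Cy5 over Cy3 used here.

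The folate cluster itself checked the labels and came first. Its 6 loci were far higher in pNZ7026 cultures in both media. With pABA, folE (lp_3297), which encodes the entry enzyme of pterin synthesis, was 65.3-fold higher (log2 6.03 ± 0.24 SE, 15 arrays, limma adjusted p = 7.98e-10). folB (lp_3299) was 61.5-fold, folK (lp_3298) 65.6-fold and folP (lp_3294), whose enzyme joins the pterin to pABA, 35.2-fold higher, with lp_3295 at 67.1-fold and lp_3296 at 45.3-fold. Without pABA the same loci were 51.0-fold (folE), 50.1-fold (folB), 53.5-fold (folK), 48.7-fold (folP), 32.6-fold (lp_3295) and 33.7-fold (lp_3296) higher, with limma adjusted p of at most 7.04e-05. The mean of the fitted effects of the 6 loci was log2 5.79 with pABA and 5.46 without. Culture means were taken on each array over those of the 6 loci not flagged, so the loci behind them varied. They differed by log2 5.93 with pABA (SD 0.76 over 3 pNZ7021 cultures and 0.22 over 3 pNZ7026 cultures) and by 5.73 without (SD 0.38 and 0.16). Both differences of culture means gave an exact permutation p of 0.1, the smallest that 3 against 3 cultures can give. Between media the cluster means with and without pABA differed by -0.23 in pNZ7021 and by -0.025 in pNZ7026 (exact p = 0.7 for both). Without culture 3 of pNZ7021 with pABA, however, the list was lower with pABA in pNZ7021 (median -0.63, camera adjusted p = 0.00836, against -0.20 and 0.447 with all cultures). Because many of these bright spots carried the poor-quality mark, lp_3295 rested on 8 arrays and folP on 9.

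**Figure D1:**
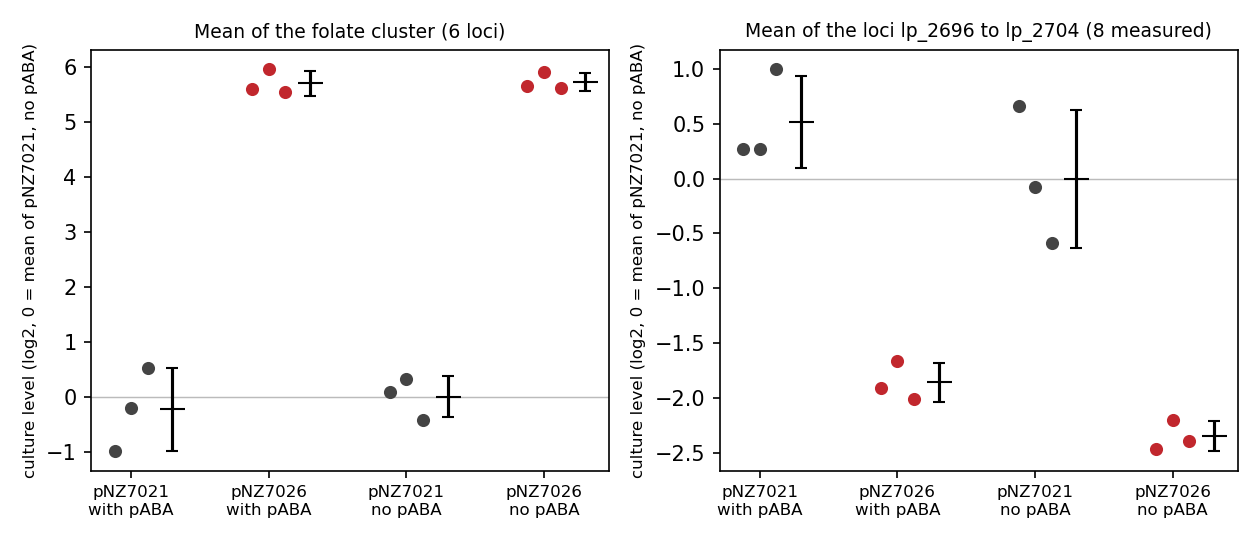
Culture levels (log2, 0 is the mean of the 3 pNZ7021 cultures without pABA) of the folate cluster mean (left) and of the mean of 8 measured loci from lp_2696 to lp_2704 (right). Points are cultures, and the bars beside them give mean and SD of 3 cultures. The pNZ7026 cultures lay at 5.55 to 5.96 for the folate cluster and at -2.46 to -1.66 for the second set, with no overlap with the pNZ7021 cultures.

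In medium with pABA the pNZ7026 strain had lower transcripts of pyrimidine synthesis and of the loci beside those genes. carB (lp_2700), for a subunit of carbamoyl phosphate synthase, fell 6.36-fold (log2 -2.67 ± 0.25 SE, limma adjusted p = 2.30e-06, 17 arrays). pyrE (lp_2697) and pyrF (lp_2698), for the enzymes that turn orotate into UMP, fell 6.25-fold and 6.20-fold. Their neighbours by locus number fell with them: lp_2702 by 6.88-fold, lp_2703 by 6.47-fold, lp_2699 by 6.03-fold, lp_2704 by 3.87-fold and lp_2696 by 2.04-fold. lp_2371 (3.29-fold) and lp_2919 (2.03-fold) completed the 10 largest falls. Besides the folate cluster, the largest rises were those of the plasmid-numbered loci lp_p2_02 (log2 2.26 ± 0.15) and lp_p2_01 (1.38 ± 0.14), of lp_0520 (2.59-fold) and of lp_2830 (2.49-fold). In pNZ7021 with pABA the single probe of lp_p2_02 was above background in 2 of 8 channels and the probes of lp_p2_01 in 16 of 24. The size of their rise therefore rested on the background correction, with lp_p2_02 at 0.70 and lp_p2_01 at 0.53 without it and at 3.34 and 1.86 with plain subtraction, all past the test.

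Among the gene lists with pABA, the pyrimidine list had 3 of 7 members lower, 0 higher and 4 not past the test (4 lower adjusted over the list alone). Its median was -0.53, with camera adjusted p = 4.21e-05 and adjusted p = 0.00079 with an estimated correlation. Of 50 ribosomal protein genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone), among them rpsL by 0.72, rplD by 1.07 and rplW by 0.76 on the log2 scale. The list's median was 0.49 (camera adjusted p = 2.53e-08, but adjusted p = 0.371 with an estimated correlation). Of 14 purine synthesis genes, 1 fell, guaB (-0.76 ± 0.19, adjusted p = 0.0147), while purN (-0.97) and purH (-1.01) did not pass. The purine median was -0.62 (camera adjusted p = 0.0308, adjusted p = 0.638 with an estimated correlation). Without culture 3 of pNZ7021 with pABA, in which purine genes were high, the pyrimidine median was -0.26 and the ribosomal median 0.23. The purine median then turned to 0.15 and passed in the opposite direction (camera adjusted p = 0.0039 at the preset correlation), so 1 culture decided its sign. Without culture 2 of that group the pyrimidine, ribosomal and purine medians were -0.79, 0.80 and -1.11. Without culture 3 of pNZ7026 with pABA the pyrimidine median was -0.31 and the purine call was lost (-0.37), as it was without culture 1 of pNZ7021 (-0.61) or of pNZ7026 (-0.47) grown without pABA, or without array 4.

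The smaller list shifts with pABA held the chaperone genes clpB (0.42), dnaJ (0.56) and dnaK (0.25), which rose. In that list of heat shock genes and proteases 3 of 12 rose and 0 fell, 5 and 0 adjusted over the list alone (camera adjusted p = 0.0308, adjusted p = 0.371 with an estimated correlation). Of 27 DNA replication and repair genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone). uvrB (0.27), a nucleotide excision repair gene, gyrB (0.31) and parE (0.46), topoisomerase subunits, rose (camera adjusted p = 0.00644, adjusted p = 0.371 with an estimated correlation). Of 20 arginine and other amino acid genes, 4 rose and 1 fell (10 and 2 adjusted over the list alone), with the histidine synthesis genes hisD at 0.59, hisB at 0.46 and hisA at 0.37 (camera adjusted p = 0.021, adjusted p = 0.55 with an estimated correlation). In the deposited log2 values the medians of these 3 lists turned to -0.15, -0.14 and -0.038, where the median of all genes also shifted by -0.13. Of the chorismate and aromatic amino acid genes 4 of 10 were lower, but the list as a whole was not past the test (camera adjusted p = 0.322). Without culture 3 of pNZ7021 with pABA it was (median -0.23, camera adjusted p = 0.0288), while the heat shock call was lost (0.11, camera adjusted p = 0.0644) and the amino acid median was 0.14. The heat shock call was also lost without culture 2 of that group (0.12) or culture 1 of pNZ7021 without pABA (0.072), and both it (0.098) and the amino acid call (0.14) were lost without culture 3 of pNZ7026 with pABA. Without array 4 the heat shock call was lost.

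In all, 402 of 2843 loci differed between the strains with pABA by limma at adjusted p of 0.05, 237 higher and 165 lower in pNZ7026, of which 14 and 11 by at least 2-fold. The count was 120 by the fit over culture levels, and it depended on single arrays and cultures. It was 235 without array 4, whose scan matched its deposited column at only r = -0.882. It was 145 without culture 1 and 130 without culture 3 of pNZ7021 with pABA, 127, 242 and 190 without cultures 1, 2 and 3 of pNZ7026 with pABA, 225 without culture 1 of pNZ7021 without pABA and 175 without culture 1 of pNZ7026 without pABA. With the scan batch as a block it was 461, and over the 6 arrays scanned in 1 batch within this medium it was 120.

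In medium without pABA the same pyrimidine genes were lower in pNZ7026. carB (lp_2700) fell 7.67-fold (log2 -2.94 ± 0.25 SE, limma adjusted p = 8.31e-07, 17 arrays), pyrE 6.39-fold and pyrF 6.28-fold. Around them lp_2702 fell 9.28-fold, lp_2703 8.12-fold, lp_2699 5.98-fold, lp_2704 4.86-fold and lp_2696 2.20-fold, and elsewhere lp_2371 fell 3.88-fold and lp_0350 2.16-fold. The largest rises besides the folate cluster were those of lp_p2_02 (log2 2.35), lp_p2_01 (1.28), lp_3414 (2.42-fold) and lp_3412 (1.76-fold). In pNZ7021 without pABA the probe of lp_p2_02 was above background in 1 of 8 channels and those of lp_p2_01 in 15 of 24. Without background correction lp_p2_02 was at 0.75 and lp_p2_01 at 0.46, and with plain subtraction at 3.44 and 1.80, all past the test. The mean of the 8 measured loci from lp_2696 to lp_2704 was lower by -2.35 without pABA (SD 0.63 over 3 pNZ7021 cultures and 0.14 over 3 pNZ7026 cultures) and by -2.38 with it (SD 0.42 and 0.18), each with the smallest exact permutation p of 0.1.

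Of the lists without pABA, the pyrimidine list again had 3 of 7 members lower and 0 higher, also when adjusted over the list alone (median -0.34, camera adjusted p = 3.03e-07, adjusted p = 9.69e-06 with an estimated correlation). In the chorismate and aromatic amino acid list, whose measured genes lead to chorismate and tryptophan, 1 of 10 fell and 7 fell adjusted over the list alone. aroA fell by 0.82 on the log2 scale (adjusted p = 0.0451), and aroE (lp_2035, -0.63) and aroF (-0.55) did not pass over all loci (camera adjusted p = 0.000822, adjusted p = 0.208 with an estimated correlation). In the purine list guaA fell by 0.47, the only 1 of 14 to pass, also adjusted over the list alone, while guaB (-0.54) and purB (-0.63) did not (camera adjusted p = 0.00932, adjusted p = 0.534 with an estimated correlation). Of the amino acid genes thrC fell by 0.36, and lysA (-0.26) and glnA (-0.34) did not pass. There 1 of 20 fell, 2 adjusted over the list alone (camera adjusted p = 0.000845, adjusted p = 0.302 with an estimated correlation). The translation list was lower (median -0.16, 4 of 25 genes positive, camera adjusted p = 0.0139), with 0 members past. Of its named genes infB (0.41) and infC (0.42) ran against that direction and ileS (-0.33) with it. The cell wall list was also lower (median -0.079, camera adjusted p = 0.0345), with 0 members past (murC, lp_2380, -0.23, murG -0.28, mraZ -0.12). Those lists were lost with an estimated correlation (adjusted p = 0.304 and adjusted p = 0.302). Without culture 1 of pNZ7026 in this medium the chorismate (-0.16), purine (-0.24), amino acid (-0.067), translation (-0.12) and cell wall (-0.040) calls were lost. The purine call was also lost without culture 1 of pNZ7026 with pABA (-0.18) or culture 3 of pNZ7021 without it (-0.21), and the purine median was -0.23 without culture 3 of pNZ7021 with pABA. The cell wall call was lost without culture 2 of pNZ7021 (-0.068) or of pNZ7026 (-0.057) in this medium. The cell wall and amino acid medians were -0.13 and -0.30 without culture 3 of pNZ7026 there.

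Without pABA, 89 of 2843 loci differed between the strains by limma, 33 higher and 56 lower in pNZ7026, of which 9 and 10 by at least 2-fold. The fit over culture levels gave 23. The count was 19, 34 and 22 without culture 1 or 2 of pNZ7021 and culture 1 of pNZ7026, 55 without culture 2 of pNZ7026, and 50 and 40 without culture 1 of pNZ7021 and of pNZ7026 with pABA. It was 212 with the scans of arrays 12 and 13 kept as labelled, 87 with the scan batch as a block, and 52 over the 6 arrays scanned in 1 batch within this medium, which hold 2 of the 3 pNZ7021 cultures.

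The strain effects in the media shared more loci than independent lists would. Of the 237 loci higher with pABA and the 33 higher without, 20 were shared against 2.75 expected (Fisher's exact p = 2.62e-14), and of the 165 and 56 lower, 32 were shared against 3.25 expected (p = 1.84e-26). These comparisons share no culture, and their errors correlated by -0.067 through the linked arrays. Across genes without the folate cluster the effects correlated with r = 0.61 (genes are not independent replicates). The shared loci include the 6 of the folate cluster, which pNZ7026 carries, and the neighbouring loci from lp_2696 to lp_2704. Fisher's test takes loci as independent, so its p-values above can be too small. Averaged over media, 459 loci differed by limma, 232 higher and 227 lower (167 by the fit over culture levels). The pyrimidine list (median -0.30, camera adjusted p = 2.35e-06, adjusted p = 7.31e-05 with an estimated correlation) had 3 of 7 lower, 6 adjusted over the list alone. The count was 238, 220, 162 and 172 without culture 3 of pNZ7021 with pABA, culture 1 of pNZ7026 with pABA, and culture 1 of pNZ7021 and of pNZ7026 without pABA.

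**Figure D2:**
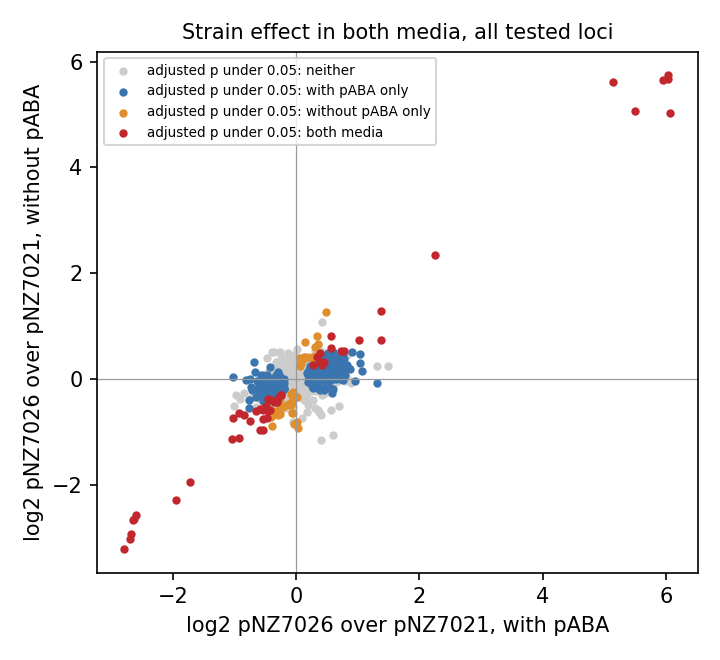
Strain effect (log2 of pNZ7026 over pNZ7021) with pABA on the x axis and without pABA on the y axis for 2843 loci, coloured by which comparison passed the limma adjusted p of 0.05. The folate cluster sits at the upper right (folE at 6.03 and 5.67) and the loci from lp_2696 to lp_2704 at the lower left (lp_2702 at -2.78 and -3.21).

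In the main fit, adding pABA to the pNZ7021 strain changed 6 loci, which the files give no symbol for. The fit over culture levels called 0 loci and a replicate block 1. No array paired pNZ7021 cultures across the media, so this effect was reached only through arrays that cross strain and medium together. lp_1112 rose 1.59-fold (log2 0.67 ± 0.12 SE, limma adjusted p = 0.0287, 17 arrays), lp_3678 rose 1.49-fold and lp_3077 rose 1.43-fold. lp_3334 fell 2.35-fold (-1.23 ± 0.22, adjusted p = 0.0287), lp_2710 fell 1.96-fold and lp_1317 fell 1.32-fold. No folate cluster locus passed: folP was at 0.46, lp_3295 at -0.60, lp_3296 at -0.42, folE at -0.32, folK at -0.074 and folB at -0.085.

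In that comparison 9 lists passed by camera at the preset correlation and none with an estimated one. The purine genes were higher with pABA by a median of 1.05, with purM at 1.41, purF at 1.09 and purH at 1.43, but 0 of 14 passed over all loci or over the list alone (camera adjusted p = 1.95e-05, adjusted p = 0.23 with an estimated correlation). The other folate and one-carbon list shares purH and purN (1.30) with it and holds metE (0.57). Its median was 0.69, with 4 of 5 past adjusted over the list alone (camera adjusted p = 0.00877, adjusted p = 0.152 with an estimated correlation). The citrate genes citD (0.44), citE (0.50) and citF (0.47) were among 4 of 5 that passed over the list alone (camera adjusted p = 0.0015, adjusted p = 0.177 with an estimated correlation). In the pyrimidine list upp (0.78) stood beside carB (lp_2700, 0.62) and pyrF (0.67), with 1 of 7 past over the list alone (camera adjusted p = 0.0255, adjusted p = 0.152 with an estimated correlation). The purine (0.060) and citrate (0.22, camera adjusted p = 0.0761) calls were lost without culture 3 of pNZ7021 with pABA, where the other folate median was 0.22. Without culture 2 of that group the purine and citrate medians were 1.67 and 0.70, and without culture 1 of pNZ7026 without pABA the purine median was 0.63. The pyrimidine call was lost without culture 1 (0.39) or 2 (0.46) of pNZ7026 with pABA and without culture 2 (0.17) or 3 (0.39) of pNZ7021 without pABA, and its median was 0.82 without culture 1 of the latter group.

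Ribosomal protein genes were lower with pABA in pNZ7021 by a median of -0.54, with rplA at -0.61, rpsM at -0.55 and rplV at -0.80 (0 of 50 past; camera adjusted p = 8.35e-10, adjusted p = 0.177 with an estimated correlation). Smaller downward medians, with 0 members past, were those of translation factors and tRNA ligases at -0.17 (argS -0.35, infC -0.52, pheT -0.23; camera adjusted p = 5.16e-05, adjusted p = 0.152 with an estimated correlation) and of DNA replication and repair at -0.12 (parE -0.41, gyrA -0.38, ssb -0.40; camera adjusted p = 0.00125, adjusted p = 0.152 with an estimated correlation). The cell wall list was at -0.13 (murC, lp_1462, -0.39, dltD -0.42, mreC -0.24; camera adjusted p = 0.0085, adjusted p = 0.177 with an estimated correlation) and the amino acid list at -0.16 (argH -0.24, hisB -0.29, proB -0.16; camera adjusted p = 0.00279, adjusted p = 0.236 with an estimated correlation). In the deposited log2 values the last 4 of these medians turned to 0.011, 0.072, 0.063 and 0.044, where the median of all genes shifted by 0.11. These lists still passed there (camera adjusted p = 1.64e-06, 0.012, 0.027 and 0.042), with medians under that shift. The ribosomal median was -0.25 and the cell wall call was lost (-0.075) without culture 3 of pNZ7021 with pABA, and without culture 2 of that group the ribosomal and cell wall medians were -0.84 and -0.21.

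Much of this rested on culture 3 of pNZ7021 with pABA. Its mean over 14 purine genes was 2.22 above the mean of all cultures, while the other 11 lay between -0.61 and 0.18, and its mean over 50 ribosomal protein genes was -0.96 against -0.12 to 0.33. The purine mean of the 3 pNZ7021 cultures with pABA was 0.63 ± 1.38 (SD) against -0.23 ± 0.050 without (exact permutation p = 0.4, n = 3). Without that culture the purine median was 0.060 (camera adjusted p = 0.235), the ribosomal median was -0.25 (camera adjusted p = 0.00023), and 0 loci passed by limma, with 226 at an unadjusted p of 0.05 against 430 with all cultures. The count was also 0 without culture 1 of pNZ7026 with pABA, without culture 2 or 3 of pNZ7021 or culture 1, 2 or 3 of pNZ7026 without pABA, and 3 without culture 2 or 3 of pNZ7026 with pABA or culture 1 of pNZ7021 without it. Leaving out array 4 or array 20, the 2 arrays of this culture, gave 2 and 0.

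**Figure D3:**
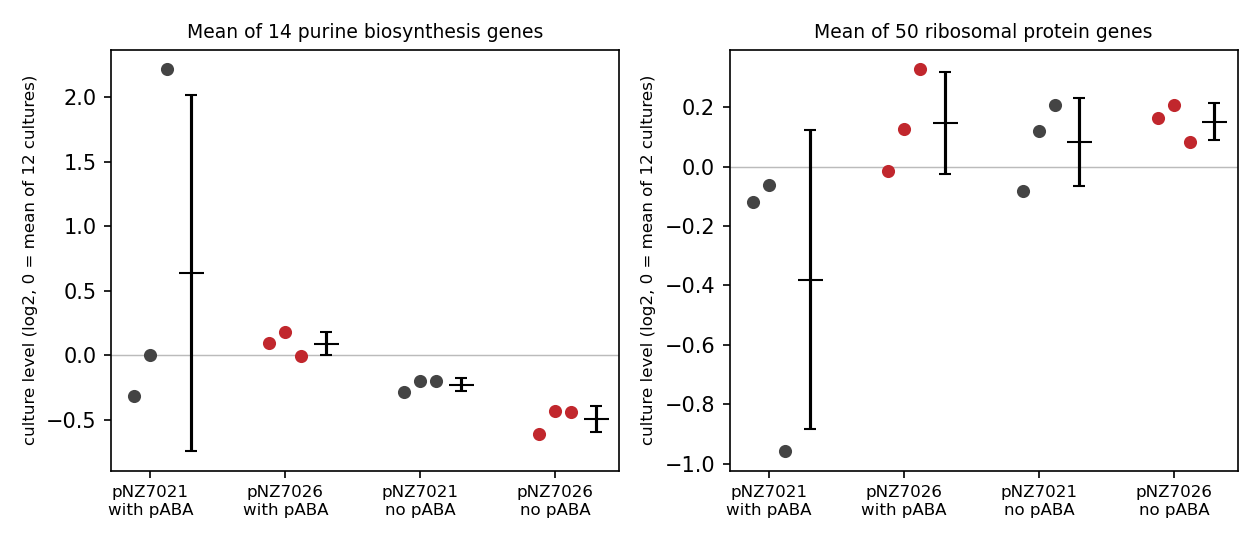
Culture levels (log2, 0 is the mean of 12 cultures) of the mean of 14 purine synthesis genes (left) and of 50 ribosomal protein genes (right). Points are cultures, and the bars beside them give mean and SD of 3 cultures. Culture 3 of pNZ7021 with pABA lay at 2.22 and -0.96, outside the ranges of -0.61 to 0.18 and -0.12 to 0.33 of the other cultures.

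In the pNZ7026 strain pABA changed 4 loci. lp_1721 rose 1.65-fold (log2 0.72 ± 0.11 SE, limma adjusted p = 0.0112, 17 arrays) and lp_1611 rose 1.46-fold, while lp_2902 fell 2.10-fold (-1.07 ± 0.19, adjusted p = 0.0193) and lp_0256 fell 1.55-fold. The folate cluster did not pass: folP was at -0.0057, lp_3295 at 0.44, lp_3296 at 0.012, folE at 0.033, folK at 0.22 and folB at 0.21. The purine mean was 0.090 ± 0.092 (SD) in the 3 cultures with pABA and -0.50 ± 0.10 in the 3 without, with no overlap (exact permutation p = 0.1, the smallest possible).

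The purine list had a median of 0.77 with pABA in pNZ7026, all 14 genes being positive, 0 past over all loci and 1 past over the list alone. purB stood at 1.59, purR, the regulator, at 0.51 and guaA at 0.35 (camera adjusted p = 3.39e-07, adjusted p = 0.145 with an estimated correlation). The citrate list was at 0.47 (citE 0.55, citD 0.47, citF 0.54), with 4 of 5 past over the list alone (camera adjusted p = 6.55e-05, adjusted p = 0.0991 with an estimated correlation). The heat shock list was at 0.14 (dnaK 0.35, groES 0.55, hrcA 0.36), with 4 higher and 1 lower over the list alone (camera adjusted p = 0.0014, adjusted p = 0.0913 with an estimated correlation). The amino acid list was at 0.15 (hisA 0.36, hisB 0.37, hisD 0.46; camera adjusted p = 6.55e-05, adjusted p = 0.128 with an estimated correlation). The other folate and one-carbon list was at 0.56 (metE 0.42, glyA 0.56, purH 0.94; camera adjusted p = 0.00811, adjusted p = 0.0991 with an estimated correlation), the chorismate list at 0.20 (aroE 0.53, trpD 0.20, aroF 0.48; camera adjusted p = 0.00135, adjusted p = 0.111 with an estimated correlation), and the pyrimidine list at 0.32 (carB, lp_2700, 0.89, pyrF 0.69, pyrE 0.55; camera adjusted p = 0.00853, adjusted p = 0.0913 with an estimated correlation). Without culture 1 of pNZ7026 without pABA the amino acid (0.039), chorismate (0.12) and other folate (0.37) calls were lost, and the purine and pyrimidine medians were 0.38 and 0.20. Without culture 1 of pNZ7026 with pABA the pyrimidine call was lost (0.15) and the other folate median was 0.37. The purine median was 0.50 without culture 3 of pNZ7021 with pABA, the pyrimidine median 0.51 without culture 3 of pNZ7026 with pABA, and the amino acid median 0.24 without culture 3 of pNZ7026 without pABA.

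The count of 4 loci moved with single cultures. It was 0 without culture 2 of either strain with pABA or culture 1 of pNZ7026 without pABA, 1 and 2 without cultures 1 and 2 of pNZ7021 without pABA, 7 without culture 1 of pNZ7021 with pABA or culture 3 without it, 17 without culture 3 of pNZ7026 with pABA and 26 without culture 3 of pNZ7021 with pABA. With the scan batch as a block it was 7, and in pNZ7021 9. The fit over culture levels and the replicate block each gave 0 in pNZ7026, and the slide as a random block gave 15.

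Averaged over the strains, pABA changed 21 loci by limma, 12 up and 9 down. The purine list was at 0.95, with 12 of 14 past adjusted over the list alone and 0 over all loci (camera adjusted p = 4.45e-09, adjusted p = 0.15 with an estimated correlation). The pyrimidine list was at 0.53, with 3 of 7 past over the list alone (camera adjusted p = 0.00315, adjusted p = 0.0498 with an estimated correlation). The citrate list was at 0.45 (camera adjusted p = 1.63e-05, adjusted p = 0.0716 with an estimated correlation) and the ribosomal list at -0.33 (camera adjusted p = 4.23e-08, adjusted p = 0.275 with an estimated correlation). The purine, pyrimidine and ribosomal medians were 0.32, 0.34 and -0.16 without culture 3 of pNZ7021 with pABA, and without culture 1 of pNZ7026 without pABA the purine median was 0.55. The count was 0 without culture 3 of pNZ7021 or culture 1 or 2 of pNZ7026 with pABA, and 0 without culture 2 or 3 of pNZ7021 or culture 3 of pNZ7026 without pABA. It was 6 without culture 2 of pNZ7021 and 37 without culture 3 of pNZ7026 with pABA, and 4, 2 and 8 without culture 1 of pNZ7021 and cultures 1 and 2 of pNZ7026 without pABA. Without array 20 or with a replicate block it was 0, and the fit over culture levels gave 9.

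No locus passed the test of whether the strain effect differed between the media: limma called 0 of 2843, with 251 at an unadjusted p of 0.05 and 0 by the fit over culture levels. The loci with the smallest p were lp_1093 (0.49), lp_1611 (0.57) and lp_2830 (1.39 ± 0.30 SE, adjusted p = 0.165) upward and lp_0139 (-0.55 ± 0.10, adjusted p = 0.162), lp_3420 (-1.04) and lp_0181 (-0.41) downward. In the folate cluster the strain effect differed by 0.36 for folE, 0.30 for folB, 0.29 for folK, -0.47 for folP, 1.04 for lp_3295 and 0.43 for lp_3296, none past the test. As a list the cluster was not past it either (median 0.33, camera adjusted p = 0.235), but was without culture 3 of pNZ7021 with pABA (0.66, camera adjusted p = 0.00955).

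In the interaction 6 lists passed by camera at the preset correlation, none with an estimated one and none with a member past over all loci. The amino acid list was at 0.27, with hisB at 0.66, hisA at 0.56 and hisH at 0.85 and 7 of 20 past over the list alone (camera adjusted p = 2.12e-07, adjusted p = 0.174 with an estimated correlation). The ribosomal list was at 0.36 (rplD 0.92, rpsL 0.55, rplX 0.71; camera adjusted p = 1.28e-05, adjusted p = 0.429 with an estimated correlation). The translation list was at 0.22 (pheT 0.34, thrS 0.53, glyS 0.42; camera adjusted p = 0.000186, adjusted p = 0.218 with an estimated correlation). The heat shock list was at 0.14, with dnaJ at 0.58, dnaK at 0.39 and hrcA at 0.35 (camera adjusted p = 0.0387, adjusted p = 0.218 with an estimated correlation). The cell wall list was at 0.11 (murC, lp_1462, 0.44, murG 0.46, mreD 0.21; camera adjusted p = 0.0118, adjusted p = 0.218 with an estimated correlation) and the DNA list at 0.084 (recO 0.30, gyrB 0.25, uvrC -0.19; camera adjusted p = 0.0428, adjusted p = 0.42 with an estimated correlation). In the deposited log2 values, where all genes shifted by -0.13, all of these medians but the ribosomal one turned negative. There the translation (-0.039) and amino acid (-0.0068) lists still passed (camera adjusted p = 9.34e-05 and 3.56e-06), with medians above that shift. The heat shock, DNA and cell wall calls were lost. The heat shock (0.095), DNA (0.064) and cell wall (0.083) calls were lost without culture 3 of pNZ7021 with pABA, each with a camera adjusted p of 0.102, and the ribosomal and translation medians were 0.17 and 0.12. The ribosomal (0.14), heat shock (0.13), cell wall (0.11) and DNA (0.092) calls were lost without culture 3 of pNZ7026 with pABA, and the translation median was 0.10. Without culture 2 of pNZ7021 with pABA the heat shock call was lost (0.17), and the ribosomal, DNA and cell wall medians were 0.64, 0.16 and 0.18. Among cultures without pABA, the heat shock call was lost without culture 1 of pNZ7021 (0.15) or culture 2 of pNZ7026 (0.11). The DNA call was lost without each of the pNZ7021 cultures of that medium (0.084, 0.11 and 0.094), cultures 1 (0.077) or 2 (0.061) of pNZ7026 there, or culture 2 of pNZ7026 with pABA (0.11). The DNA median was 0.13 without culture 1 of pNZ7026 with pABA and 0.13 without culture 3 of pNZ7026 without pABA, where the cell wall median was 0.18. Without array 4 the heat shock, DNA and cell wall calls were lost. The lists of ATP synthase, glycolysis and lactate, and fatty acid synthesis passed in none of the 7 comparisons (smallest camera adjusted p 0.217, 0.179 and 0.235).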

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

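Of the tests in this part, those on single cultures and probes behind the pyrimidine run, on a role of pABA in it, on a pABA effect in every pNZ7021 culture and on the identity of scans were chosen after the results were seen.

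The pyrimidine genes carB (lp_2700), pyrE and pyrF and their neighbours from lp_2696 to lp_2704 were lower in pNZ7026 cultures in both media, without overlap between the strains. The tables argue against a dye bias (mean log2 ratio -2.27 ± 0.67 SD over 6 arrays with pNZ7026 in Cy5 and -2.75 ± 0.47 over 6 with it in Cy3), against 1 culture carrying the fall (weakest mean strain effect -2.29 with each culture left out) and against a few cross-hybridising probes (100% of 23 probes lay under -0.5 in both media). A fall that needs added pABA is also argued against. The strain effect with pABA minus that without was 0.19 (95% interval -0.56 to 0.93) in the fit over arrays. The unweighted means of culture levels gave strain effects of -2.38 with pABA and -2.35 without. A strain effect that does not depend on added pABA may therefore account for the lower pyrimidine transcripts, as a hypothesis found and tested on the same data. Whether it comes from the folate genes on the plasmid, from the plasmid load or from a change elsewhere in that strain was not tested. Folate levels were not part of these data, so a role of folate made without added pABA was not tested either.

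Culture 3 of pNZ7021 with pABA had high purine and low ribosomal protein transcripts. A faulty scan of array 4 is argued against, since without it the purine mean of this culture still lay 2.52 above the mean of the other 2 of its group, and so is a dye effect shared by all arrays (mean dye term of the purine genes -0.028). A pABA effect in every pNZ7021 culture is argued against by the purine median of 0.060 without this culture. On the scans of arrays 4 and 20 its purine mean exceeded its partner's by 2.13 and 2.90. It was in Cy5 on both, so the fit could not tell a fault of its Cy5 labelling from a change in the culture. On the scans of arrays 13 and 5, outside the fit and read as array 5 with this culture in Cy3, the excess was 2.36 and 1.83. That reading of these scans was not certain. A different state of this culture at harvest may account for the values, but no biological explanation of a single culture was tested.

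Some scans went against their labels: read as arrays 4 and 5, those of arrays 12 and 13 correlated with the ratios predicted from the other arrays at r = 0.847 each, against 0.294 and 0.022 as labelled, so the smaller gain was 0.553, which is consistent with scans stored under the wrong arrays. The scan of array 4, kept in the comparisons, then fits array 4 less well (r = 0.686, residual 0.402) than that of array 12 (residual 0.264), and it matched its deposited column at only -0.882, so which scan holds array 4 stayed open. Array 7, which pairs pNZ7021 cultures 2 and 1 with pABA, correlated at 0.46 with the ratio predicted for the order of the design text and at -0.43 as labelled, whereas array 15 fitted its label (0.588 against -0.675). Array 7 closes a loop with arrays 1 and 2 alone, and these 3 had the same misfit (0.594), with array 2 at r = -0.104 as labelled. The folate cluster ratios of arrays 1 and 2 (7.16 and -5.33) argue against a turn of either, but cannot tell pNZ7021 culture 1 from 2, so whether array 7 was turned or those cultures were exchanged stayed open (412 loci differed between the strains with pABA with array 7 turned).

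Gene lists for which the strain effect differed between the media by camera were ribosomal proteins (median 0.36), translation factors and tRNA ligases (0.22), heat shock genes and proteases (0.14), DNA replication and repair (0.084), cell wall and division (0.11) and arginine and other amino acids (0.27), none of which passed with an estimated correlation. Of these, the ribosomal, heat shock, DNA and cell wall calls were lost without 1, 5, 8 and 2 of the 12 cultures left out singly. On array 15, 87.6% of gene spots lay above background in Cy5 against 94.1% to 99.1% on the other arrays within pABA-free medium, the 1 such outlier among 15 array measures, where chance gives 0.75. Among 43 probes outside the annotated loci, mtf_9#16 was higher in pNZ7026, by 2.28 with pABA (limma adjusted p = 7.49e-12) and 1.55 without. The other mtf_9 probes, mtf_9#1 to mtf_9#15, lay between -0.12 and 0.27 with pABA and passed in neither medium. The rise was thus that of a single probe. The folate cluster, outside the comparisons, stood at 7.35 on the scan of array 5, at -4.37 on that of array 12 and at 6.12 on that of array 13, and the scan of array 5 is shared by array 6, whose label gives the opposite sign. With the ratios predicted from the other arrays that shared scan correlated at 0.791 read as array 5. Read as array 6 it gave -0.569 with dyes as labelled and 0.539 with dyes reversed. These values favour array 5, but its match with the deposited column of array 6 (r = 0.995) goes the other way.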

How the results depend on the processing

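The fits without array 4 or array 20, the other readings of arrays 12 and 13, the 19 scans assigned as in the series table, array 7 alone turned, poor spots kept and the series table with medians set to 0 were chosen after seeing the data. Over all settings, the 66 gene results past the threshold gave 2532 values, of which 2149 kept their direction and their side of the threshold, 379 lost significance and 4 reversed. The 103 gene results not past it gave 3890 values, of which 61 passed and 107 changed sign with neither past. The 51 list results past it gave 1996 values, with 198 weaker and 20 reversed, and the 54 not past it 2114, with 76 stronger, 7 reversed and 215 that changed sign with neither past. A list counted as reversed when its median turned sign with either fit past the test. This took no account of a shift of all genes, and some of these lists still passed camera. Without a filter on dim probes the counts between the strains were 402 and 89, and with only probes above background in all channels 336 and 88. Dim signal did limit the size of single loci. For strain with pABA, lp_p2_02 was at 0.70 without background correction and at 3.34 with plain subtraction. Aquantile leaves log ratios unchanged by construction. Unless the construction of a setting shows the cause, the cause was not tested.

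Counts are given in the order strain with pABA (402 loci), strain without pABA (89), pABA in pNZ7021 (6), pABA in pNZ7026 (4), interaction (0), strain averaged (459) and pABA averaged (21). At adjusted p of 0.01 they were 156, 31, 0, 0, 0, 225 and 1, and with at least a 2-fold change 25, 19, 1, 1, 0, 19 and 2. Arrays taken as independent gave 717, 286, 11, 65, 6, 876 and 35, which ignores that cultures are shared. The fit over 12 culture levels gave 120, 23, 0, 0, 0, 167 and 9. Without background correction the second was 51, the fourth 1 and the last 9, and with the median over probes the last was 9. Without a dye term pABA in pNZ7026 gave 11, with the scan batch as a block 7, and with the slide as a random block 15, where pABA averaged gave 36. Over arrays within the medium the strain effect gave 120 with pABA and 52 without.

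With the design text's order for arrays 7 and 15 the strain effect without pABA gave 149, and pABA gave 2 in pNZ7021 and 18 in pNZ7026, and with array 7 alone turned 10 in pNZ7026. The doubled scan read as array 5 gave 14 for pABA in pNZ7026. Read as array 6 with dyes as labelled, which the folate cluster contradicts, it gave 4 and 43 for the strain effects, 1 for pABA in pNZ7021, 99 for strain averaged and 2 for pABA averaged, and with dyes reversed 623 for strain with pABA and 13 and 7 for pABA in pNZ7021 and pNZ7026. Arrays 12 and 13 kept as labelled gave 212 for strain without pABA and 0 and 17 for pABA in pNZ7021 and pNZ7026. Read as arrays 4 and 5 they gave 12 for pABA in pNZ7021. The 19 scans assigned as in the series table gave 18 and 16 for pABA in the strains, 2 for the interaction and 34 for pABA averaged. Without array 4 strain with pABA gave 235 and pABA in pNZ7021 gave 2, and without array 20 pABA in pNZ7021 and pABA averaged gave 0.

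The series table gave 1637 (110 higher, 1527 lower), 58, 23, 1, 4, 837 (90 higher, 747 lower) and 0. Its columns are not centred, and the median of all genes shifted by -0.13 for strain with pABA and 0.11 for pABA in pNZ7021. With medians set to 0 it gave 883 (418 higher, 465 lower), 104, 40, 17, 42, 699 and 14. With each of the 12 cultures left out, the counts ranged over 127 to 424, 19 to 120, 0 to 9, 0 to 26, 0 to 1, 162 to 476 and 0 to 37.

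With pABA, pNZ7021 and pNZ7026 cultures of the same number correlated at 0.385, -0.0197 and 0.305, and those of different numbers at -0.37 to 0.23. Without pABA the same numbers correlated at 0.151, -0.407 and 0.0112, and different numbers at -0.253 to 0.326. The culture number thus gave no pairing that held for all cultures, but a pairing of some cultures with pABA is not excluded. A replicate block gave 1 and 0 for pABA in pNZ7021 and pNZ7026, 3 for the interaction and 0 for pABA averaged.

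The folate cluster's strain effect with and without pABA was 5.05 and 5.03 without background correction, 3.97 and 4.13 with the doubled scan read as array 6 as labelled, 5.00 and 4.81 in the series table and 5.14 and 4.81 with its medians set to 0. With each culture left out it ranged over 5.36 to 6.30 and 5.51 to 5.88.

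Reversed values under the doubled scan read as array 6 as labelled were -0.065 for lp_1035 (strain with pABA) and -0.15 for the pyrimidine list (pABA in pNZ7021). In the series table lp_0772 was at -0.063, lp_0006 at -0.035 and lp_2556 at -0.043 for strain with pABA. There the lists turned to -0.15 for heat shock, -0.14 for DNA repair and -0.038 for amino acids (strain with pABA), to 0.011 for translation, 0.072 for DNA repair, 0.0095 for glycolysis, 0.063 for cell wall and 0.044 for amino acids (pABA in pNZ7021), and to -0.17 for ATP synthase (pABA in pNZ7026). They also turned to -0.039, -0.14, -0.11, -0.15 and -0.0068 for translation, heat shock, DNA repair, cell wall and amino acids (interaction), to -0.057 for DNA repair (strain averaged) and to 0.022 for cell wall (pABA averaged). With medians set to 0 only values of the heat shock, cell wall and ATP synthase lists stayed reversed. Heat shock was at -0.0048 for strain with pABA and -0.0023 for the interaction, cell wall at -0.012 (interaction) and ATP synthase at -0.15 (pABA in pNZ7026). Arrays 12 and 13 as labelled turned the amino acid list to 0.00084 (strain without pABA) and the purine list to 0.48 (interaction). With each culture left out, the purine list ranged over -1.11 to 0.15 (strain with pABA) and -0.72 to 0.49 (interaction), the heat shock list over -0.011 to 0.038 (strain averaged) and the chorismate list over -0.020 to 0.14 (pABA averaged), and the upper ends for purine were reached without culture 3 of pNZ7021 with pABA.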

Other observations

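The counts of other splits of the cultures were planned, and the values by locus and without culture 3 of pNZ7021 with pABA in this part were chosen after the results were seen.

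Averaged over media, the pNZ7026 strain had lower transcripts of the chorismate and aromatic amino acid list, where 4 of 10 genes passed (5 adjusted over the list alone) at a median of -0.20 (camera adjusted p = 0.0159, adjusted p = 0.437 with an estimated correlation). The other folate and one-carbon list was at -0.64 with 1 of 5 lower (camera adjusted p = 0.0459, adjusted p = 0.437 with an estimated correlation), and 5 of 50 ribosomal protein genes were higher at a median of 0.34 (camera adjusted p = 2.28e-06, adjusted p = 0.516 with an estimated correlation). The other folate call was lost without culture 3 of pNZ7021 with pABA (-0.13, camera adjusted p = 0.131), where the ribosomal median was 0.12, and without culture 2 of that group the ribosomal median was 0.53 and the chorismate call was lost (-0.17). Without culture 1 of pNZ7026 without pABA the chorismate (-0.16) and other folate (-0.55) calls were lost. The other folate call was also lost without culture 2 (-0.64) or 3 (-0.47) of pNZ7026 with pABA, culture 2 (-0.66) or 3 (-0.57) of pNZ7021 without it and culture 2 of pNZ7026 without it (-0.70), and without array 4. The purine list was lower at -0.45, with 2 of 14 genes past (camera adjusted p = 0.00509, adjusted p = 0.563 with an estimated correlation). Its call was lost without culture 3 of pNZ7021 with pABA (-0.0030, camera adjusted p = 0.874). The DNA replication and repair list was at 0.098, with 3 of 27 genes higher (camera adjusted p = 0.0159, adjusted p = 0.437 with an estimated correlation). Its call was lost without 1 of the 12 cultures. Loci that passed with the strain averaged over media, named here after their values were seen, were lp_1386 (0.76), lp_0145 (0.71), lp_3413 (0.75), lp_3134 (-0.79), lp_0018 (-0.78) and lp_2390 (-0.78).

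Of the 21 loci that passed with pABA averaged over strains, lp_3271 rose most (2.14, limma adjusted p = 0.0408). mmuM (lp_1298), for a homocysteine methyltransferase, rose by 0.39, lp_1105 rose by 0.45, and thiE (lp_0115), for a thiamine synthesis enzyme, fell by 0.19. lp_2901 fell by 0.60 beside lp_2902 (-0.83), and lp_0254 by 0.40 beside lp_0256 (-0.37). These were named after their values were seen.

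Without culture 3 of pNZ7021 with pABA, the purine list was higher with pABA in pNZ7026 by a median of 0.50 (camera adjusted p = 5.92e-22), was not past the test in pNZ7021 (0.060, camera adjusted p = 0.235), and the interaction had a median of 0.49 (camera adjusted p = 8.94e-12). With all cultures the purine interaction was not past the test and had the opposite sign (median -0.22, camera adjusted p = 0.832, adjusted p = 0.974 with an estimated correlation), so its direction rested on that culture. The tests without that culture were at the preset correlation, and the purine genes correlated by 0.773 in the estimate over all arrays.

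For the 6 cultures of a comparison only 10 splits exist, too few for a share under 0.05. The real split alone reached its count (1 of 10) in each case: 402 against at most 0 for strain with pABA, 89 against 14 for strain without, 6 against 1 for pABA in pNZ7021 and 4 against 0 for pABA in pNZ7026. For strain averaged 1 of 100 splits of the 12 cultures, the real one, reached 459 (highest other 288). That share is under 0.05 and is the smallest these splits can give, and another grouping still gave 288 loci. For pABA averaged 2 of 100 splits reached 21, a share under 0.05, but the other of these gave more loci (23) than the real one, and the count was 0 without each of 6 single cultures, so the 21 loci rest on little. For the interaction the real count was 0, so that 100 of 100 splits reached it by construction. The split with 23 kept the pNZ7021 cultures divided by medium and so held the pABA difference within that strain. The split with 21 divided both strains by medium, with the media of pNZ7021 exchanged, and so was the pABA effect averaged over strains. A split with 17 mixed the media in both strains, and the cause of its count was not tested.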
